A study of Mus musculus with 12 samples.

How the data were processed

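RNA samples from MC38 cells, 12 in number, were measured on Illumina mouse bead arrays, 1 array per sample, with 4 arrays for each of 3 groups. The groups and the replicate numbers 1 to 4 came from the sample titles. Their abbreviations were read as control cells, cells given the short isoform CEACAM1-S and cells given the long isoform CEACAM1-L. All cells had grown for 72 h in medium with 10% serum. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase treatment and turned into biotin-labelled cRNA. The labels name 4 samples per cell line and do not say whether these were separate cultures, clones or extractions of the same culture, so p-values measure only the spread between these arrays, which may be technical. Every column was matched to a sample, leaving 0 unmapped. Chip and position of each array are not given in the sources used here.

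The deposited non-normalized table holds 1 signal intensity and 1 detection p-value for each probe and array, per the file headers. The lowest intensities of the 12 arrays lay between 68.6 and 81.4 units, so no background had been subtracted from them. The detection p-value places a probe's signal among the negative control beads of its array. The deposited series values are on a log2 scale, with array medians between 7.07 and 7.08 that had been made nearly equal by the authors. Each column of them correlated best with the log2 intensities of its own array (r between 0.9957 and 0.9999 across probes). These columns were not centred per probe, and their normalization method is not given in the sources used here. The submitters' processing notes name lumi 2.6.0 without its role. The scanner and its software are likewise not given in the sources used here. No direction had to be settled, since the arrays have 1 colour.

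Probes were named through the platform annotation. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 were unnamed here. Gene IDs of 34807 of these probes matched the reference annotation of assembly GRCm38.p6, which changed 0 symbols. Intensities were processed with neqc in limma 3.58.1 (R 4.3.3): normexp background correction with the background inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p-value under 0.05 on at least 4 of the 12 arrays were kept, which left 16330, of which 14091 had 1 symbol, 7 had several and 2232 were unnamed. Each gene was represented by its kept probe with the highest mean over the 12 arrays, which gave 9100 tested genes out of 19057 named ones; 3429 tested genes had more than 1 kept probe. A probe named by several symbols or by none entered no gene test.

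A linear model with 1 mean per group was fitted to all 12 arrays with lmFit, and the 3 differences between groups were tested with eBayes and a mean-variance trend (9 residual and 15.5 prior degrees of freedom). All tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05; every adjusted p-value given for a gene is limma's. A second count kept the genes that also differed by at least 2-fold, a log2 difference of 1. Errors of group means are SDs over 4 arrays and errors of log2 differences are the standard errors of the fit. Where a probe was detected on none of a group's arrays, the fold is given as "at least": the mean of the brighter group over the mean, for the dim group, of the higher of the probe's own signal and the lowest signal among detected probes of each array. The number of arrays limits the precision. Between 14717 and 16071 probes were detected per array (32.5 to 35.5%), and a change in a gene under that floor could not be seen.

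Before the data were examined, 23 gene lists were fixed, along with the fits, the alternatives and the rule for the genes named. The rule took Ceacam1, Dcn and Epha2, then the 8 largest positive and 8 largest negative differences per comparison among genes past the threshold whose 4 arrays in 1 group all lay above or below the other 4, then up to 3 members per list with the largest difference past the threshold (the member with the lowest p where none passed). Predicted and unnamed genes were left out of it, and not every list member it selected is described. The lists covered matrix and adhesion (collagens, matrix glycoproteins and basement membrane, matrix proteases and inhibitors, small leucine-rich proteoglycans, integrins, the CEACAM family, epithelial and mesenchymal genes), signalling (decorin-linked receptors, Eph receptors and ephrins, ErbB and Ras response, Wnt targets, cytokines and chemokines), cell state (cell cycle, p53 targets, glycolysis and hypoxia, unfolded protein and amino acid stress, sterol biosynthesis, interferon-stimulated genes, class I antigen presentation) and markers of other cell types. The lists hold 642 memberships, of which 594 had a named probe and 353 were tested. Of the 23 lists, 19 had at least 5 tested genes and were tested with camera, which compares a list's genes with all other tested genes, using a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests only the net direction of a list's own genes, were run beside it. The lists for other cell types a culture could hold were those for immune, endothelial, secretory and goblet cells.

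The procedure was tested on simulated intensities with known changes for the CEACAM1-L comparison with control, over 10534 genes. It called 38 of 67 genes changed 1.5-fold (56.7%), 65 of 67 changed 2-fold (97%) and 66 of 66 changed 4-fold (100%), 20 of 30 genes raised 1.5-fold together as a simulated list (66.7%), and 12 of 10304 unchanged genes (0.12%). The changed genes all had a probe well above background, the simulated spread of a gene was capped, and noise was independent between genes. Recovery of changes near the detection floor or in genes with a larger spread was not tested and may be lower.

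Alternatives fixed in advance were: no background correction, an offset of 50, scaling to the median or cyclic loess in place of quantiles, the authors' processed log2 values, other filters on detection, the mean of a gene's probes or all probes, the replicate number as a block, only the 2 groups compared, array weights, other empirical Bayes settings, a stricter threshold, limma's treat, the other list tests, and leaving out each array in turn. Scaling to the median used all 45281 probes of an array, most of which were undetected. Alternatives added after seeing the data were the 2 sets of 6 arrays that the residuals formed, used as a block or singly, and leaving out the genes of chromosomes 5 and 9. Because both isoform lines were set against the same 4 control arrays, their overlap was compared with 100 simulations of unchanged groups and with the 6 ways of splitting the controls. Chromosomes were taken from the reference annotation, whose assembly may differ from the one the array was designed on, so no positions are given.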

Results

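Gene expression was compared between control MC38 mouse colon cancer cells and the same cells given either main splice isoform of CEACAM1. CEACAM1 is a cell adhesion protein of the immunoglobulin superfamily. Its long isoform, CEACAM1-L, ends in a cytoplasmic tail with inhibitory tyrosine motifs that the short isoform, CEACAM1-S, lacks. There were 4 arrays each for control, CEACAM1-S and CEACAM1-L cells, all harvested after 72 h in 10% serum. Raw signals had array medians between 86.6 and 103 units and means between 208 and 391 units, and 14717 to 16071 of 45281 probes were detected per array. Across the 9100 tested genes, arrays of 1 group correlated at r between 0.9856 and 0.9935, and arrays of different groups at r between 0.9587 and 0.9838. The first 3 principal components held 40.7%, 22.2% and 8.46% of the variance. Within groups, the arrays fell into a pair of sets that held 2 arrays of each group. Set A was control 2 and 3, CEACAM1-S 1 and 4 and CEACAM1-L 2 and 3, with highest raw signals between 30290 and 40614 units, and set B was the other 6, with 17443 to 27138 units.

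Ceacam1, the gene by which the lines were made to differ, was read by 4 probes. The probe with the highest signal was detected on all 12 arrays, at 4.92 ± 0.06 log2 units in control, 8.33 ± 0.39 in CEACAM1-S and 6.55 ± 0.12 in CEACAM1-L cells (SD, n = 4). Its control values sat just above the detection threshold. The log2 difference from control was 3.40 ± 0.17 (SE) in CEACAM1-S (10.6-fold, adjusted p = 4.02e-13) and 1.63 ± 0.17 in CEACAM1-L cells (3.09-fold, adjusted p = 7.4e-08), and CEACAM1-L lay below CEACAM1-S by −1.78 ± 0.17 (adjusted p = 5.18e-08). A pair of further probes was detected on no control array and on all 8 isoform arrays, at least 1.55-fold and at least 1.32-fold higher in CEACAM1-L and at least 3.31-fold and at least 5.54-fold higher in CEACAM1-S cells. The remaining probe was detected on no array. Which exons the probes cover was not analysed here, so the values do not separate the isoforms. Without background correction the Ceacam1 differences were 0.61 for CEACAM1-L, 1.77 for CEACAM1-S and −1.16 between them, and in the authors' processed values, whose method is not given, 0.54, 1.60 and −1.06, all past the threshold.

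Dcn and Epha2 are named in the title of the series and may have been chosen on these samples, so their values here are not independent evidence. Dcn encodes decorin, a small leucine-rich proteoglycan of the extracellular matrix that binds collagen and growth factor receptors. Dcn rose in both isoform lines, from 7.02 ± 0.29 in control to 9.82 ± 0.09 in CEACAM1-L and 10.31 ± 0.18 in CEACAM1-S cells (SD, n = 4). The log2 differences were 2.80 ± 0.13 (SE) in CEACAM1-L (6.98-fold, adjusted p = 5.26e-14) and 3.29 ± 0.13 in CEACAM1-S cells (9.75-fold, adjusted p = 2.5e-15). A second Dcn probe, detected on 3 of 4 control arrays and on all isoform arrays, gave 1.87 and 2.37, and another 2 probes were detected on no array. Dcn was lower in CEACAM1-L than in CEACAM1-S cells by −0.48 ± 0.13 (adjusted p = 0.00617). That difference did not pass with scaling to the median (−0.62, adjusted p = 0.497) or in set B alone (−0.33, adjusted p = 0.286), and it was −0.63 in set A.

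Epha2, a receptor tyrosine kinase for ephrin-A ligands, fell in both isoform lines. Its single probe read 9.32 ± 0.04 in control, 8.72 ± 0.28 in CEACAM1-L and 8.48 ± 0.17 in CEACAM1-S cells (SD, n = 4). The log2 difference was −0.60 ± 0.13 (SE) in CEACAM1-L (adjusted p = 5.29e-04) and −0.84 ± 0.13 in CEACAM1-S cells (adjusted p = 1.88e-05). The CEACAM1-L and CEACAM1-S lines differed by 0.24 ± 0.13 (adjusted p = 0.174), which did not pass. With scaling to the median the differences from control were −0.74 and −0.87 and did not pass (adjusted p = 0.214 and 0.215), with standard errors of 0.35 for both. Within set A they were −0.66 and −0.72, and within set B −0.54 and −0.95. By the reference assembly GRCm38.p6, Ceacam1, Dcn and Epha2 lie on chromosomes 7, 10 and 4.

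**Figure D1:**
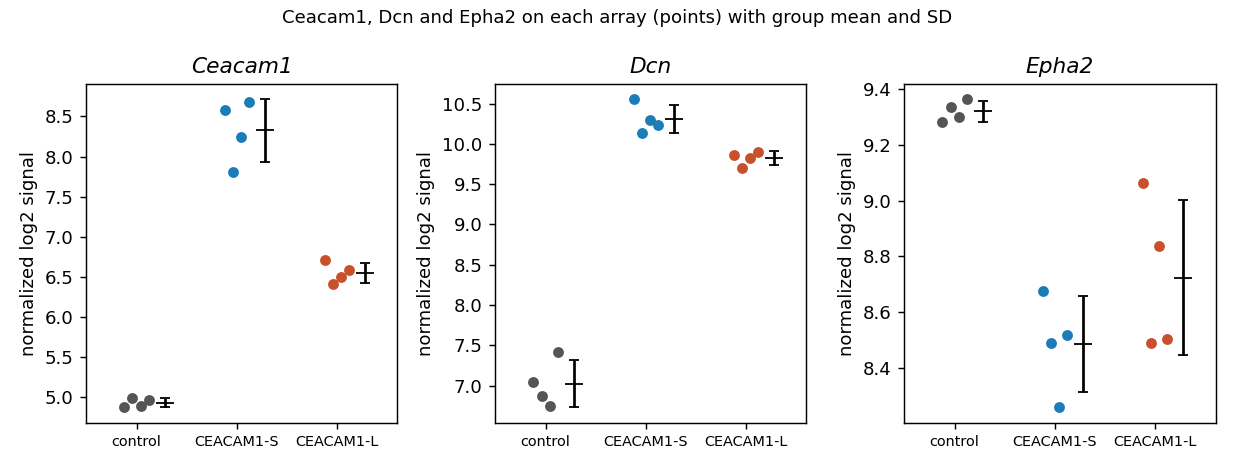
Normalized log2 signal of Ceacam1, Dcn and Epha2 on each of the 12 arrays (points), with the mean and SD of 4 arrays per group (bars). Dcn means were 9.82 in CEACAM1-L and 10.31 in CEACAM1-S against 7.02 in control cells, and Epha2 means were 8.72 and 8.48 against 9.32.

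In CEACAM1-L cells against control, interferon-stimulated genes and genes of sterol synthesis rose as groups. The largest rises were those of Prxl2a, a peroxiredoxin-like protein, by 4.69 ± 0.30 (SE) log2 units (25.8-fold, adjusted p = 1.3e-11), and Dbp, a transcription factor of the circadian clock output, by 3.70 ± 0.19 (13-fold, adjusted p = 2.95e-13). Cryab, a small heat shock protein, rose 10.6-fold. Ogn, a small leucine-rich proteoglycan like Dcn, rose by 3.03 ± 0.18 (adjusted p = 3.48e-12) and was detected on 1 of 4 control arrays. Stbd1, a glycogen-binding protein, and Cldn4, a tight junction claudin, were detected on no control array and were at least 7.61-fold and at least 6.84-fold higher. Serpinb9g (8.89-fold) and Serpinb9f (at least 7.07-fold), serine protease inhibitors, are near-identical paralogs whose probes may read each other, so their separate values are uncertain.

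The largest fall in CEACAM1-L cells was that of S100a7a, a calcium-binding S100 protein, by −4.06 ± 0.19 (16.7-fold, adjusted p = 5.64e-14). Csn3, a milk casein, fell 12.3-fold, Cyp3a13, a cytochrome P450, 11.7-fold, Nppb, the precursor of brain natriuretic peptide, 10.3-fold, and Stra6, a receptor for retinol-binding protein, 7.43-fold. Gvin1, a large interferon-inducible GTPase, fell 6.1-fold and was detected on 1 of 4 CEACAM1-L arrays, Btbd3 fell 6.09-fold, and Pate14 was detected on no CEACAM1-L array and at least 5.20-fold lower. Each of these genes had all 4 arrays of 1 group on 1 side of the other 4. In all, 3290 of 9100 genes differed (1652 higher, 1638 lower), 451 of them at least 2-fold (255 higher, 196 lower). With scaling to the median 637 differed (252 higher, 385 lower, so 39.6% were higher in place of 50.2%), with a median over all genes of −0.11, and 131 differed at least 2-fold without background correction.

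Of the 29 tested interferon-stimulated genes, 17 rose, 0 fell and 12 did not pass (camera adjusted p = 9.31e-06, and adjusted p = 0.0319 with an estimated correlation). With p-values adjusted over the list alone, 18 rose. Ifit3, an inhibitor of viral translation, rose by 1.86 ± 0.15 (SE), Usp18, which removes the ubiquitin-like modifier ISG15, by 1.56 ± 0.21 and Dhx58, a sensor of viral RNA, by 1.54 ± 0.19. Among 16 tested genes of sterol biosynthesis, 8 rose and 0 fell (camera adjusted p = 0.00219, and adjusted p = 0.0319 with an estimated correlation), with the mevalonate pathway enzymes Mvk at 1.38 ± 0.21 and Mvd at 1.16 ± 0.14 and the sterol sensor Insig1 at 1.16 ± 0.16. These were the only 2 lists past the threshold under both forms of camera.

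Matrix genes rose in CEACAM1-L cells under camera's preset correlation. Among collagens, 8 of 14 rose and 0 fell (adjusted p = 0.00285, and adjusted p = 0.148 with an estimated correlation), led by Col6a2 at 1.24 ± 0.14. Among matrix glycoproteins and basement membrane genes, 9 of 17 rose and 2 fell (adjusted p = 0.00285, and adjusted p = 0.0671 with an estimated correlation). Thbs2 and Thbs1, which encode thrombospondins, rose by 1.43 ± 0.11 and 1.18 ± 0.15, and Vcan, a large proteoglycan, by 1.24 ± 0.16. In the class I antigen presentation list 8 of 21 rose and 1 fell (adjusted p = 0.0267, and adjusted p = 0.126 with an estimated correlation), with H2-T10 at 0.91 ± 0.12. In the cell cycle list 12 of 38 rose and 2 fell (adjusted p = 0.0267, and adjusted p = 0.126 with an estimated correlation), with Cenpa, a centromeric histone, at 0.84 ± 0.09. The counts of these 4 lists and of the sterol list were the same when adjusted over the list alone. The matrix glycoprotein call was also lost with no filter on detection (adjusted p = 0.0665), and the class I and cell cycle calls with scaling to the median (adjusted p = 0.218 and 0.232), as were those of H2-T10 (0.77 ± 0.35, adjusted p = 0.199) and Cenpa (0.73 ± 0.33, 0.194).

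A further 4 lists fell in CEACAM1-L cells. In the ErbB and Ras response list 8 of 16 fell and 2 rose (camera adjusted p = 0.0267, and adjusted p = 0.126 with an estimated correlation); Dusp5, a phosphatase that switches off ERK, fell by 2.10 on the log2 scale, the growth factor gene Hbegf by 1.64 and Fos, detected on 2 of 4 CEACAM1-L arrays, by 1.46. In the endothelial list 3 of 6 fell and 0 rose (adjusted p = 0.0267, and adjusted p = 0.126 with an estimated correlation): Egfl7, a secreted vascular factor, by 1.16 from a control level of 9.40, and Flt1 and Cdh5, detected on no CEACAM1-L array, were at least 2.25-fold and at least 1.33-fold lower. In the Wnt target list 4 of 7 fell and 1 rose (adjusted p = 0.0307, and adjusted p = 0.234 with an estimated correlation), with Dkk3, which is grouped with the Wnt inhibitors, at −1.98 ± 0.12, Myc at −1.08 ± 0.15 and the receptor gene Fzd7 at 1.39 ± 0.18; adjusted over the list alone, 2 rose. Among cytokines and chemokines 10 of 19 fell and 3 rose (adjusted p = 0.0396, and adjusted p = 0.126 with an estimated correlation), with the chemokine Cxcl1 at −1.66 ± 0.14 and Il15 at 1.68 ± 0.17; adjusted over the list alone, 12 fell. The Wnt call was lost without control 4 (adjusted p = 0.0511), with scaling to the median (0.142), without a detection filter (0.545), with the mean of a gene's probes (0.0721) and without trend (0.0682). The cytokine call was lost without control 1, 3 or 4 (adjusted p = 0.0721, 0.098 and 0.123), with either stricter detection filter (0.155 and 0.547), with array weights (0.051) and without the genes of chromosomes 5 and 9 (0.197). In set B alone the endothelial call was lost (adjusted p = 0.0678).

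Of the remaining lists in CEACAM1-L cells, 9 were tested and did not pass with camera. Members higher and lower were 6 and 3 of 17 decorin-linked receptors and growth factors, 3 and 2 of 10 Eph receptors and ephrins, 1 and 4 of 11 integrins, 5 and 5 of 19 mesenchymal genes, 5 and 5 of 23 matrix proteases and inhibitors, 1 and 0 of 10 epithelial genes, 3 and 3 of 17 p53 targets, 6 and 10 of 27 glycolysis and hypoxia genes and 9 and 8 of 28 genes of the unfolded protein response. Ephb4 rose by 1.29 ± 0.11 and the ephrin gene Efna1 by 1.11 ± 0.20, opposite to Epha2. Adjusted over the list alone, 4 Eph genes were higher, 2 integrins were higher and 5 lower, and 12 glycolysis genes were lower. Median and mean log2 difference had opposite signs for the epithelial list (−0.10 and 0.20, test direction up), matrix proteases (−0.04 and 0.03, up) and p53 targets (0.03 and −0.03, down). Fry gave 16 of 19 lists a net direction. Of 16 small leucine-rich proteoglycans, 4 were tested and 2 rose, Ogn and Dcn. Ceacam1 was the only tested gene of its family. Of 26 immune markers 2 were tested and neither passed, with Cd14 at −0.26 ± 0.17 (adjusted p = 0.24), and of 14 secretory markers 1 was tested, Clca1, at −0.03 ± 0.18 (adjusted p = 0.92).

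**Figure D2:**
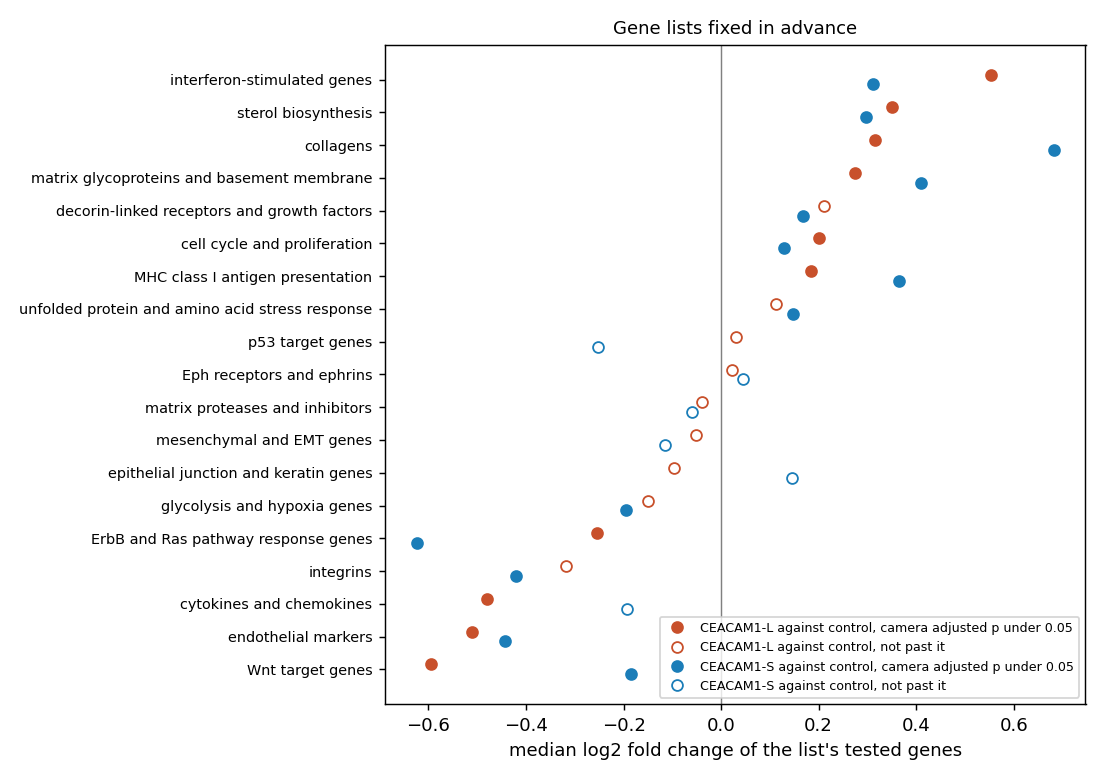
Median log2 difference from control over the tested genes of each of the 19 tested lists (horizontal axis), for CEACAM1-L and CEACAM1-S cells, filled where camera's adjusted p with a preset correlation was under 0.05. With an estimated correlation 2 of the 10 CEACAM1-L calls and 5 of the 13 CEACAM1-S calls remained under it.

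In CEACAM1-S cells against control, collagens and class I antigen presentation genes rose as groups and ErbB and Ras response genes fell. Ceacam1 and Dcn had the largest rises. Ogn rose by 2.99 ± 0.18 (SE) (adjusted p = 6.25e-12, detected on 1 of 4 control arrays). Napsa, an aspartic protease, rose 6.52-fold (adjusted p = 3.28e-07), the zinc transporter gene Slc39a4 6.04-fold, Dennd2a 5.63-fold with detection on 1 of 4 control arrays, and Fcgrt, the neonatal Fc receptor, 5.54-fold (adjusted p = 5.5e-13). Macc1, a transcriptional regulator linked to colon cancer metastasis, was detected on no control array and was at least 4.92-fold higher. S100a7a had the largest fall, −3.93 ± 0.19 (15.2-fold, adjusted p = 1.26e-13).

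Pate14 was detected on no CEACAM1-S array and was at least 5.24-fold lower. The claudin gene Cldn6 fell 5.91-fold (adjusted p = 1.26e-13), Cyp3a13 5.8-fold, Dusp5 5.46-fold, Btn1a1, a milk fat globule protein, 5.19-fold with detection on 1 of 4 CEACAM1-S arrays, the imprinted gene Phlda2 4.64-fold and Tigit, an inhibitory receptor of lymphocytes, 4.15-fold. In all, 2148 of 9100 genes differed (1110 higher, 1038 lower), 242 of them at least 2-fold (140 higher, 102 lower). With scaling to the median 276 differed, and 70 differed at least 2-fold without background correction.

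Among collagens 9 of 14 rose and 0 fell in CEACAM1-S cells (camera adjusted p = 7.79e-07, and adjusted p = 0.0359 with an estimated correlation). Col6a2 rose by 2.32 ± 0.14 (SE), Col6a1 by 1.49 ± 0.10 and Col1a1, detected on 2 of 4 control arrays, by 1.47 ± 0.20. Among matrix glycoproteins and basement membrane genes 10 of 17 rose and 3 fell (adjusted p = 4.38e-04, and adjusted p = 0.0333 with an estimated correlation), with Tgfbi at 1.00 ± 0.17 and the laminin gene Lamb2 at 1.07 ± 0.14. In the class I antigen presentation list 12 of 21 rose and 0 fell (adjusted p = 2.16e-06, and adjusted p = 0.0113 with an estimated correlation), led by the immunoproteasome genes Psmb9 at 1.46 ± 0.17, Psmb10 at 0.90 ± 0.10 and Psmb8 at 0.89 ± 0.09. In the sterol list 6 of 16 rose and 0 fell (adjusted p = 0.00477, and adjusted p = 0.034 with an estimated correlation). In the ErbB and Ras response list 11 of 16 fell and 1 rose (adjusted p = 9.47e-07, and adjusted p = 0.015 with an estimated correlation), with Hbegf at −1.74 ± 0.13 and Phlda1, an early growth factor response gene, at −1.10 ± 0.11. Adjusted over the list alone, 11 matrix glycoprotein genes rose and 12 ErbB and Ras genes fell, and the other 3 counts did not change. With scaling to the median, the calls of Lamb2 (1.05 ± 0.35, adjusted p = 0.0816), Psmb10 (0.88 ± 0.34, 0.182) and Psmb8 (0.87 ± 0.33, 0.184) ended with differences about as large and larger standard errors.

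Another 8 lists passed with the preset correlation in CEACAM1-S cells and not with an estimated one. Interferon-stimulated genes numbered 12 higher and 3 lower of 29 (adjusted p = 0.00581, and adjusted p = 0.0639 with an estimated correlation), led by the guanylate-binding protein gene Gbp2 at 1.70 ± 0.14. Cell cycle genes numbered 13 higher and 2 lower of 38 (adjusted p = 0.0101, and adjusted p = 0.0644 with an estimated correlation; 0.168 with scaling to the median). Decorin-linked receptors and growth factors numbered 5 higher and 1 lower of 17 (adjusted p = 0.0299, and adjusted p = 0.0644 with an estimated correlation), with Tgfbr2 at 1.25 ± 0.10 and Tgfb3 at 1.20 ± 0.16; the call was lost without control 2 (0.053), without the genes of chromosomes 5 and 9 (0.057) and with the mean of a gene's probes (0.115). Genes of the unfolded protein response numbered 9 higher and 3 lower of 28 (adjusted p = 0.0299, and adjusted p = 0.0639 with an estimated correlation), with Sdf2l1 and Pdia6, which act in the endoplasmic reticulum, at 1.48 ± 0.14 and 1.05 ± 0.18; the call was lost among genes detected on all 12 arrays (0.0586) and with the mean of a gene's probes (0.0549). Adjusted over the list alone, 13 interferon-stimulated, 14 cell cycle, 6 decorin-linked and 12 unfolded protein response genes were higher.

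The other 4 of these lists were lower in CEACAM1-S cells. Endothelial markers numbered 0 higher and 3 lower of 6 (camera adjusted p = 0.0299, and adjusted p = 0.104 with an estimated correlation; 0.0544 without control 2 and 0.0667 without a detection filter). Wnt targets numbered 0 higher and 3 lower of 7 (adjusted p = 0.0299, and adjusted p = 0.204 with an estimated correlation), namely Myc at −1.07 ± 0.15, the adhesion receptor gene Cd44 at −0.96 ± 0.08 and Sox9 at −0.67 ± 0.09; the call was lost without control 4 (0.0636), with scaling to the median (0.118), without a detection filter (0.404), with the mean of a gene's probes (0.0854) and without trend (0.0603). Integrins numbered 1 higher and 4 lower of 11 (adjusted p = 0.0307, and adjusted p = 0.0696 with an estimated correlation), with Itgav at −1.01 ± 0.17; the call was lost without control 4 (0.0579), with scaling to the median (0.102), without a detection filter (0.0667), with array weights (0.0557) and with the mean of a gene's probes (0.115), which also ended that of Itgav (−0.33, 0.107). Glycolysis and hypoxia genes numbered 3 higher and 10 lower of 27 (adjusted p = 0.0376, and adjusted p = 0.104 with an estimated correlation); the call was lost without control 4 (0.0927) or CEACAM1-S 2 (0.07), with scaling to the median (0.102), among genes detected on all 12 arrays (0.0654), with the mean of a gene's probes (0.0854), with array weights (0.0727) and without trend (0.0645). In set A alone the integrin and glycolysis calls were lost (adjusted p = 0.106 and 0.16), and in set B alone the integrin, Wnt, endothelial and unfolded protein response calls (adjusted p = 0.0586, 0.0598, 0.0827 and 0.0827). Scaling to the median also ended the calls of Myc (−1.09 ± 0.35, adjusted p = 0.0611), Cd44 (−0.96 ± 0.33, 0.103), Sox9 (−0.68 ± 0.33, 0.429) and Itgav (−1.03 ± 0.34, 0.0636), again with differences about as large and larger standard errors. With adjustment over the list alone, 7 integrins were lower, 4 glycolysis genes higher and 1 Wnt target higher.

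The 6 tested lists that did not pass in CEACAM1-S cells had these members higher and lower: 6 and 8 of 19 cytokines and chemokines, 1 and 1 of 10 Eph receptors and ephrins, 0 and 2 of 10 epithelial genes, 0 and 6 of 23 matrix proteases, 4 and 6 of 19 mesenchymal genes and 4 and 6 of 17 p53 targets. Ccl7, a monocyte chemokine, rose by 1.62 ± 0.15 (SE), and Csf2, detected on no CEACAM1-S array, was at least 2.38-fold lower. Krt8, an epithelial keratin, fell by 1.03 on the log2 scale. When adjusted over the list alone, 1 matrix protease gene was higher and 7 p53 targets were lower. The median and mean differed in sign for the epithelial list (0.15 and −0.12, test direction down) and the Eph list (0.04 and −0.04, down). Fry gave 15 of 19 lists a net direction. Of the immune markers, Cd14 fell by 1.01 on the log2 scale (adjusted p = 6.34e-05; −1.05 ± 0.35 and 0.079 with scaling to the median), and Clca1 was at 0.05 ± 0.18 (adjusted p = 0.875).

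CEACAM1-L and CEACAM1-S cells were also compared directly. These lines differed in Ceacam1 signal as well (6.55 against 8.33) and in the median of the genes of chromosome 9 (−0.29) and chromosome 5 (0.19). Isoform, Ceacam1 level and the history of each line therefore cannot be told apart. Differences said to be between the isoforms are differences between these lines. C2, a component of the complement system, was higher in CEACAM1-L cells by 3.97 ± 0.31 (SE) log2 units (15.7-fold, adjusted p = 1.83e-09), with a level of 9.47 ± 0.18 against 5.50 ± 1.11 (SD, n = 4) and detection on 3 of 4 CEACAM1-S arrays. Prxl2a was higher by 3.22 ± 0.30 (9.34-fold, adjusted p = 2.98e-08), Cldn4 6.73-fold, Stbd1 5.72-fold, Olfm1 5.33-fold and the transcription factor gene Gata6 5.1-fold. Of these, Cldn4 and Gata6 were detected on 2 and Stbd1 on 3 of 4 CEACAM1-S arrays. The paralogs Serpinb9g and Serpinb9f were 7.09-fold and 6.89-fold higher, with the same uncertainty as above and detection on 2 and 1 of 4 CEACAM1-S arrays. Napsa was lower in CEACAM1-L cells by −3.26 ± 0.30 (9.58-fold, adjusted p = 2.69e-08), with detection on 1 of 4 CEACAM1-L arrays.

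Other genes lower in CEACAM1-L than in CEACAM1-S cells were Mfsd6 (7-fold, detected on 2 of 4 CEACAM1-L arrays), Csn3 (5.58-fold), Nnmt, which methylates nicotinamide (4.97-fold), Btbd19 (4.22-fold), the phospholipase gene Pla1a (3.85-fold), the cadherin gene Cdh26 (3.84-fold) and Stra6 (3.55-fold). In all, 2382 of 9100 genes differed (1204 higher, 1178 lower in CEACAM1-L), 257 of them at least 2-fold (142 higher, 115 lower). With scaling to the median 293 differed, and 57 differed at least 2-fold without background correction. Genes that differed from control in CEACAM1-L only and also between the isoforms numbered 1104, and those that differed in CEACAM1-S only and between the isoforms 433. A further 365 genes had moved the same way in both lines and differed between them.

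Of the 19 tested lists, 0 passed between the isoforms with camera; 6 had an unadjusted p under 0.05, 0 passed with an estimated correlation, and fry gave 12 a net direction. Interferon-stimulated genes came nearest, with 12 higher and 2 lower of 29 in CEACAM1-L cells (adjusted p = 0.0531); Cxcl10, an interferon-induced chemokine, was at 1.25 ± 0.14 (SE) and Gbp2 at −1.13 ± 0.14. This list passed without control 1 (adjusted p = 0.0292), control 2 (0.0407), control 3 (0.0455), CEACAM1-S 1 (0.0407), CEACAM1-S 2 (0.0197), CEACAM1-S 4 (0.0487), CEACAM1-L 1 (0.0192) or CEACAM1-L 2 (0.0469). It also passed without background correction (0.0321), with scaling to the median (0.0356), cyclic loess (0.0495), the authors' values (0.0261), an offset of 50 (0.0474), no detection filter (0.0161), either stricter one (0.0148 and 0.0127), the mean of a gene's probes (0.0212), only the 2 groups (0.0311), array weights (0.0264), the array set as a block (0.0392), and in set A (0.00873) or set B (0.046) alone. The interferon list did not pass with the replicate number as a block, without trend or with robust eBayes. Nor did it pass without control 4, CEACAM1-S 3, CEACAM1-L 3 or CEACAM1-L 4. Leaving out the genes of chromosomes 5 and 9, with Cxcl10 among them, also left it short of the threshold. The count of 0 lists therefore held for the main settings and not for most of the other fits. Collagens had 1 member higher and 5 lower of 14 (adjusted p = 0.0538; 0.037 without CEACAM1-S 2, 0.0192 without CEACAM1-L 1, 0.0322 with scaling to the median, 0.0495 with cyclic loess, 0.0264 with array weights and 0.00424 in set A), with Col1a1 at −1.29 ± 0.20 and Col6a2 at −1.08 ± 0.14. ErbB and Ras response genes had 6 higher and 0 lower of 16 (adjusted p = 0.0538; 0.0407 without CEACAM1-S 1, 0.0469 without CEACAM1-L 2, 0.0495 with cyclic loess, 0.0271 among genes detected on all 12 arrays and 0.0178 in set B), with the ERK phosphatase gene Dusp4 at 1.80 ± 0.16. Class I antigen presentation genes had 0 higher and 4 lower of 21 (adjusted p = 0.0538; 0.0474 without CEACAM1-L 1, 0.0495 with cyclic loess, 0.0245 without a detection filter and 0.0291 with the mean of a gene's probes). Eph receptors and ephrins, with 4 higher and 0 lower of 10 (adjusted p = 0.141), passed with camera only among genes detected on all 12 arrays (0.0271).

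Single members of other lists differed between the isoforms. Mmp10 and Mmp13, matrix metalloproteinases, were higher in CEACAM1-L cells by 1.70 ± 0.22 (SE) and 1.39 ± 0.24, Mmp13 being detected on 1 of 4 CEACAM1-S arrays and short of the threshold in set B alone (0.89, adjusted p = 0.086). The neuronal enolase gene Eno2 was higher by 1.35 ± 0.13 and Efna1 by 1.01 ± 0.20 (adjusted p = 4.79e-04; 0.91 ± 0.32 and 0.0979 with scaling to the median, 0.82 and 0.0729 in set B). Tgfbr2, a receptor for TGF-beta, was lower by −1.57 ± 0.10 (adjusted p = 8.75e-11), the monocyte chemokine genes Ccl2 and Ccl7 by −1.46 ± 0.22 and −1.31 ± 0.15, Il34 by −1.21 ± 0.14, Snai2, a transcriptional repressor of epithelial genes, by −1.22 ± 0.14 and Dkk3 by −1.80 ± 0.12. Members higher and lower were 2 and 6 of 19 cytokines, 6 and 2 of 23 matrix proteases, 5 and 6 of 17 matrix glycoprotein genes, 3 and 3 of 17 decorin-linked genes, 4 and 1 of 16 sterol genes, 2 and 7 of 28 unfolded protein response genes, 6 and 4 of 38 cell cycle genes, 5 and 1 of 17 p53 targets, 3 and 3 of 27 glycolysis genes, 2 and 3 of 11 integrins, 3 and 1 of 10 epithelial genes, 3 and 5 of 19 mesenchymal genes, 3 and 2 of 7 Wnt targets and 0 and 0 of 6 endothelial markers. Adjusted over the list alone, 13 interferon-stimulated, 3 cytokine, 6 matrix glycoprotein and 6 sterol genes were higher and 2 epithelial genes lower. Median and mean differed in sign for the cell cycle list (−0.00 and 0.02, up), glycolysis (−0.01 and 0.03, test direction up) and mesenchymal genes (0.01 and −0.08, down), and integrins had a median of 0, a mean of −0.05 and the test direction up.

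CEACAM1-L and CEACAM1-S cells shared many of their differences from control. Higher in both were 659 genes and lower in both 650, while 41 were higher in CEACAM1-L and lower in CEACAM1-S cells and 32 the reverse; Dcn, Ogn, S100a7a, Pate14 and Dusp5 were among those that moved together. Across the 9100 genes, which are not independent replicates, the log2 differences correlated at r = 0.611, and 70.9% had the same sign. Sharing the control arrays alone gave r = 0.501, 66.6% with the same sign and 0 genes in both directions in 100 simulations of unchanged groups. These groups held no effects, so the 0 does not show how many shared calls the common controls add where effects are real. Lists of these lengths drawn independently would share 202 and 187 genes. With the controls split between the comparisons, r averaged 0.508 (range 0.477 to 0.54 over 6 splits), with 423 genes higher and 377 lower in both, against 118 and 102 for independent lists. The split comparisons have no array in common, so the simulated 0.501 is not the reference for this r. The covariance of the differences was 0.125, against 0.0126 in the simulations, a difference of 0.113, and 0.111 with split controls.

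Genes of chromosome 9 were higher as a set in CEACAM1-S cells and those of chromosome 5 in CEACAM1-L cells, a comparison made after the data were examined. Of 508 tested genes on chromosome 9, 240 were higher and 12 lower in CEACAM1-S cells, with a median log2 difference of 0.37 (camera adjusted p = 1.57e-21, and adjusted p = 0.0178 with an estimated correlation). Of 625 tested genes on chromosome 5, 264 were higher and 50 lower in CEACAM1-L cells, with a median of 0.26 (adjusted p = 4.27e-09, and adjusted p = 0.019 with an estimated correlation). Medians of the other 18 chromosomes lay between −0.06 and 0.01 in CEACAM1-S and between −0.09 and 0.02 in CEACAM1-L cells. In the opposite line the medians were 0.07 for chromosome 9 in CEACAM1-L cells (127 higher, 63 lower, adjusted p = 0.305) and 0.05 for chromosome 5 in CEACAM1-S cells (121 higher, 56 lower, adjusted p = 0.614), where its first part was at 0.14 and its second at −0.01. Between the isoforms chromosome 9 was at −0.29 (camera adjusted p = 3.93e-12, and adjusted p = 0.0547 with an estimated correlation) and chromosome 5 at 0.19 (adjusted p = 1.38e-08, and adjusted p = 0.026 with an estimated correlation). Of the genes named in the text, Tgfbr2, Lamb2, Cryab, Stra6, Pate14, Nnmt, Mmp10 and Mmp13 lie on chromosome 9, and Stbd1, Cldn4, Csn3, Cyp3a13, Mvk, Insig1, Cxcl1, Cxcl10, Ephb4, Flt1, Cenpa and Clock on chromosome 5. Without the genes of both chromosomes, 1255 genes were higher and 1513 lower in CEACAM1-L cells than in control, 727 higher and 941 lower in CEACAM1-S cells, and 988 higher and 936 lower in CEACAM1-L than in CEACAM1-S cells. Higher and lower genes had been near even before the removal, and the values were not normalized again. A surplus of lower genes against control therefore follows from leaving out chromosomes picked for their higher genes, and is no separate result.

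**Figure D3:**
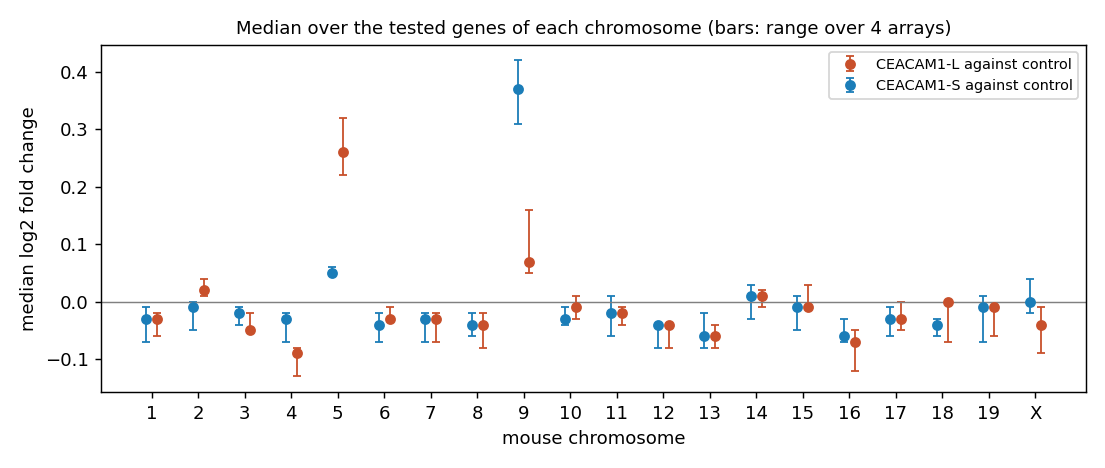
Median log2 difference from control over the tested genes of each mouse chromosome (horizontal axis) for CEACAM1-L and CEACAM1-S cells, with bars for the range of the median over the 4 arrays of the line. The arrays ranged from 0.31 to 0.42 for chromosome 9 in CEACAM1-S and from 0.22 to 0.32 for chromosome 5 in CEACAM1-L cells.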

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

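Tests chosen only after the result was seen were those of the second Dcn probe and of the shared control line, the tests of the highest runs of genes on chromosomes 5 and 9, and the share of genes above 0 on each, which the medians already seen made partly known. The other tests in this part were set before their results were seen, although the medians of both chromosomes had been noticed in the data.

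In 21 of 306 groups of 4 arrays, over the genes named in the text, the highest or lowest array stood apart, its gap to the nearest other array taking most of the group's range; chance gives about 1 in 20. The share of the range was 0.946 for Dbp in CEACAM1-S cells (array 2), 0.894 for Serpinb9f (2), 0.878 for Fcgrt (2), 0.844 for Psmb10 (2) and 0.883 for Dusp4 (2) in the same line. It was 0.85 for Pate14 (4), 0.871 for Cxcl10 (4), 0.833 for Fos (1) and 0.984 for Tgfb3 (3), also in CEACAM1-S cells. In CEACAM1-L cells it was 0.935 for Csn3 (4), 0.886 for Napsa (4), 0.893 for Nnmt (4), 0.856 for Btbd19 (4) and 0.946 for Csf2 (3). In control cells it was 0.914 for Mvd (1), 0.872 for Tgfbr2 (1), 0.893 for Tigit (2), 0.861 for Bop1 (3), 0.876 for Csf2 (4), 0.879 for Btn1a1 (4) and 0.952 for Tgfbi (4). On CEACAM1-L 4, Napsa (6.44 against 4.41 to 4.64), Csn3, Nnmt and Btbd19 lay toward the CEACAM1-S level. On CEACAM1-S 2, Dbp (10.64 against 9.4 to 9.46), Serpinb9f and Dusp4 lay toward the CEACAM1-L level, while Fcgrt and Psmb10 lay below their group. Without CEACAM1-L 4, 310 genes differed at least 2-fold between the isoforms, against 257 with it. Why these arrays leaned this way was not tested.

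Among the 2232 kept probes without a gene name here, which entered no gene test, 42 were at least 2-fold higher and 33 lower in CEACAM1-L than in control cells, and 27 higher and 16 lower in CEACAM1-S cells.

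Every other way of splitting the 8 arrays of a comparison into 4 and 4 was tried, 35 splits in each. For the count of differing genes only the real split, 1 of 35, reached its result in each comparison: 3290 against a highest other of 0 for CEACAM1-L, 2148 against 2 for CEACAM1-S and 2382 against 0 between the isoforms. The same held for differences of at least 2-fold (451 against 0, 242 against 1 and 257 against 0). It also held, by smaller margins, for the lists of CEACAM1-L (10 against 7) and CEACAM1-S (13 against 9). A share of 1 of 35 is the smallest these splits can give, so they argue against chance assignment of arrays without excluding it. The arrays of a line may be technical replicates, and any lasting difference between lines would then give such counts. For lists between the isoforms the real count was 0, which all 35 splits reach whatever the data (highest other 3), so the splits say nothing about chance there.

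Dcn was higher and Epha2 lower in both isoform lines. Each array set held 2 arrays of every group, so a shift between the sets cancels from these comparisons. The sets were formed from deviations within groups, so they could not reveal a batch that coincides with a group. Neither the Dcn nor the Epha2 difference came from 1 set alone. The smallest of the 4 within-set differences of Dcn was 2.65, and the one nearest to 0 for Epha2 was −0.54. A Dcn probe that reads something else does not account for the rise, since the other detected probe rose in both lines, by 1.87 in CEACAM1-L cells, where its rise was smaller. A change in the single control line, as against an effect of CEACAM1, cannot be told apart: both lines were compared with the same control, and the lines themselves differed in Dcn by −0.48. An effect shared by both isoforms stays open as a hypothesis, untested without a second control line.

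Genes of chromosome 9 in CEACAM1-S and of chromosome 5 in CEACAM1-L cells were higher together. A few strongly changed genes do not account for this, as 84.3% of tested genes on chromosome 9 and 74.1% on chromosome 5 lay above 0. Nor did the rise come from 1 array set alone, as the lower within-set medians were 0.37 and 0.26. A shift between the sets, each with 2 arrays of every group, cancels from these comparisons. An extra copy of the chromosome in part or all of the cells of each line may be the source. The first and second part were both higher, with medians of 0.34 and 0.41 on chromosome 9 and 0.33 and 0.21 on chromosome 5. These parts differed by 0.07 and 0.12. On chromosome 15, which had no such rise, the parts differed by 0.19 in CEACAM1-L cells, so parts this alike do not by themselves speak for an extra copy. On chromosome 5 a whole extra copy does not by itself account for the highest run of 25 neighbouring genes against control, from Dnajb6 to Ift172. That run had a median of 0.85, against at most 0.77 in 1000 shuffles of gene order (permutation p = 0.001, the smallest they can give). It was tested against the 1 control line only. The parts of chromosome 5 were at 0.14 and −0.01 in CEACAM1-S cells against control, and at 0.19 and 0.20 between the isoforms. A change in the control line therefore cannot be told apart as a source of the uneven rise. On chromosome 9 no run stood out in this way: its highest, from Apeh to Atrip with a median of 0.53, was reached in 875 of 1000 shuffles (permutation p = 0.9). Runs on the other chromosomes were looked at without a test. No DNA was measured here, and a difference between the lines that arose during selection, independent of CEACAM1, remains open.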

How the results depend on the processing

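All alternatives were planned except the array sets and the removal of chromosomes 5 and 9, chosen after the data were examined. No result reversed. Over all 31 alternatives Ceacam1 in each comparison and Dcn against control stayed past the threshold, and Epha2 between the isoforms stayed short of it (0.07 to 0.41). Causes were not tested unless given. Genes differing at least 2-fold numbered 131, 70 and 57 without background correction (CEACAM1-L, CEACAM1-S, and CEACAM1-L against CEACAM1-S, in that order throughout), 122, 64 and 48 in the authors' values, whose processing differs in unknown ways, and 232, 105 and 116 with an offset of 50.

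Scaling to the median left 637, 276 and 293 differing genes and ended the calls of Epha2 against control (−0.74 and −0.87) and of Dcn between the isoforms (−0.62), which were no smaller than before, because standard errors rose (from 0.13 to 0.35 for Epha2 and from 0.13 to 0.34 for Dcn); of 212 values of named genes it ended 81, while each other planned setting ended 0 to 11, set A 14 and set B 32. Under it the share of higher genes in CEACAM1-L was 39.6% (50.2% with quantiles) and between the isoforms 41.6% (50.5%). That median was taken over all probes of an array, of which 32.5 to 35.5% were detected, so it lay among undetected probes. Raw array medians ran from 86.6 to 103 units and means from 208 to 391 units. This scaling need not have evened out differences in signal range between arrays. The larger standard errors and lower shares under it may stem from this, which was not tested. All kept probes, being more tests, gave 5190 and 3593 probes (first and last comparison), 716 at least 2-fold in the first. The stricter threshold of 0.01 left 1326 and 1488 genes in the last 2 comparisons, and treat against 1.5-fold called 155 and 159 there in place of the counts at least 2-fold. Lists past the threshold against control numbered 2 and 5 with an estimated correlation, 16 with fry in CEACAM1-L and 8 with the mean of a gene's probes in CEACAM1-S. Between the isoforms, where none passed, 1 did without background correction, in the authors' values, with an offset of 50, with detection p under 0.01, with only the 2 groups or with the array set as a block; 2 with median scaling, no filter, the mean of probes, array weights, set A or set B; 3 among genes detected on all 12 arrays; 4 with cyclic loess; and 12 with fry. The correlation of the effects was 0.582 with array weights, 0.538 in set A and 0.648 in set B. Set B alone gave 1678, 893 and 677 genes and ended the Dcn call between the isoforms (−0.33). Set A, with as many arrays, gave 1565 higher and 1652 lower, 999 and 937, and 1246 and 1327.

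Leaving out each array in turn gave 2918 to 3349, 1770 to 2206 and 1935 to 2487 differing genes, 0 to 3 lists between the isoforms (3 without CEACAM1-L 1) and a correlation of 0.566 to 0.627. Replicate numbers do not pair the arrays: of 12 same-numbered pairs 1 had a correlation of deviations over 0.1 (range −0.2 to 0.19), and 0 arrays correlated best with their own number. With the replicate number as a block 3154, 1972 and 2250 genes differed, and it changed no other call among these results. A chip block was not run, since no chip is given in the sources used here.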

Other observations

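The 3 gene lists in this part were chosen after the data were examined, as were the tests of the other E-box-driven genes and of the opposite clock phase; the test within the array sets was set before its result was seen.

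Genes of the circadian clock driven through E-boxes were higher in CEACAM1-L cells. Beside Dbp, the nuclear receptor gene Nr1d1 rose by 2.13 ± 0.20 (SE) log2 units (adjusted p = 8.11e-09), Tef, a relative of Dbp, by 1.20 ± 0.21, and the period genes Per3 by 1.05 ± 0.18, Per2 by 0.95 ± 0.19 and Per1 by 0.79 ± 0.15. Of 11 tested genes of this list 7 were higher and 0 lower in CEACAM1-L than in control cells (camera adjusted p = 8.63e-05 over the 3 lists, and adjusted p = 0.00988 with an estimated correlation). In CEACAM1-S cells 3 were higher and 1 lower (adjusted p = 0.218, and adjusted p = 0.334 with an estimated correlation). The difference between the isoforms was itself past the threshold, with 7 higher and 0 lower in CEACAM1-L cells (adjusted p = 6.14e-05, and adjusted p = 0.00783 with an estimated correlation).

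Genes of oxidant and xenobiotic defence were higher in CEACAM1-L cells, 12 of 20 against 1 lower (camera adjusted p = 6.09e-08, and adjusted p = 6.14e-04 with an estimated correlation). The quinone reductase gene Nqo1 rose by 2.37 ± 0.15 (SE), the glutathione transferase gene Gstm1 by 1.58 ± 0.12 and Gclm, a subunit of the enzyme that starts glutathione synthesis, by 1.06 ± 0.11. In CEACAM1-S cells 7 were higher and 0 lower (adjusted p = 4.38e-04, and adjusted p = 0.01 with an estimated correlation), with Nqo1 at 0.76 ± 0.15. Genes of ribosome biogenesis were lower, 24 of 34 in CEACAM1-L cells (adjusted p = 6.9e-12, and adjusted p = 9.63e-04 with an estimated correlation) and 11 of 34 in CEACAM1-S cells (adjusted p = 2.42e-05, and adjusted p = 0.0151 with an estimated correlation), with 0 higher in either. Pes1 fell by 2.32 and Bop1 by 1.46 on the log2 scale in CEACAM1-L cells; both act in the maturation of the large ribosomal subunit. Because the lists were picked on these data, their p-values are too small to count as independent tests.

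The rise of the 6 clock genes did not come from 1 array set alone, as their smallest within-set difference in CEACAM1-L cells was 0.77. A shift between the sets, each with 2 arrays of every group, cancels from the comparison. It is not settled whether all E-box-driven genes moved: the 5 other tested members had a median of 0.11 and went both ways. Another phase of the clock at harvest, an effect of culture timing, may be a candidate explanation; the 2 tested genes of the opposite phase, Arntl at −0.35 (adjusted p = 0.15) and Clock at −0.41 (adjusted p = 0.013), had a median of −0.38, and so few genes leave it open. A single time point of 72 h cannot tell a phase shift from a steady change, and an effect of CEACAM1-L itself stays untested.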
